A study of Drosophila melanogaster with 5 samples.

How the data were processed

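The series measured DNA recovered by CHART-seq with roX2 oligonucleotides, with sense oligonucleotides as control, and input DNA, in Drosophila S2 cells that express MSL3-TAP. Groups and replicate numbers were taken from the labels: roX2 CHART with RNase elution (2 libraries), roX2 CHART with biotin elution (1), sense control (1) and input control (1). Reads were aligned with Bowtie to dm3, per the submitters' processing notes, which give no version. For each library the deposited values are a signal: tag density smoothed with a bandwidth of 200 bp at steps of 35 bp, per the file headers. How duplicates, strand shift and repeated positions were treated is not given in the sources used here. The deposited peak list holds 200-bp positions called on the RNase libraries combined, per the series design text and the file headers. Its score column is 1 for all peaks, so the deposited score ranks nothing, and the peak caller and its threshold are not given in the sources used here.

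The planned analysis assumed reads, and the densities were converted to estimated tags. Isolated stretches of signal had the shape of a Gaussian of the stated bandwidth. Their lowest height was 1 in the biotin-eluted, sense and input densities and 2 in both RNase densities. There none of the 1013 and 829 isolated stretches was an odd multiple of a height of 1, with sums rounded to the nearest multiple. In every library all isolated stretches lay within 0.05 of a whole multiple of the lowest. The sum of signal was therefore divided by 14.3 per tag in the first case and by 28.6 in the second. If the RNase densities count each read as 2, the estimate gives reads. If they hold pairs of reads, it gives pairs. Folds do not depend on this factor except through the pseudocount, while depths and intervals do. Smoothing moves part of a tag's weight into neighbouring windows, so folds in 200-bp windows are lowered at narrow peaks.

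Tags in a window were scaled per 1e+06 tags on X, 2L, 2R, 3L, 3R and 4, after adding 1 tag, and divided by the same value in input. Sequences of the heterochromatic arms were used only for deposited peaks and for totals. The X to autosome ratio used tags on X over tags on 2L, 2R, 3L and 3R, divided by that ratio in input. Bins of 1000 bp with at least 10 input tags were called at a fold of 4 or more. RNase bins were those called in both libraries. Intervals are exact binomial intervals at 95%. The peak medians were placed among 10000 random sets of X windows matched on input tags and at least 1000 bp from peaks. Lists were described with exact binomial and Fisher's exact tests. For values set over the shared input, unchanged libraries were simulated from the input, and the input tags were split at random into separate parts, 1 for each library. The distance from peaks used bin centres and peak centres.

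Depth set the precision: a median bin held 28.0 and 15.8 tags in the RNase libraries, so a fold near 4 in a single bin of these libraries is uncertain. The bin rule was tested on simulated data at the depth of each library: of 50 bins with a true fold of 4 it called 48% to 56%, all of those at 6 and 8, none at 2, and at most 2 of 114855 unchanged bins. In the simulation of unchanged libraries from the input, the rule called 2 bins on X and 15 off X for RNase replicate 2, 1 off X for replicate 1 and 1 off X for the sense control. The conversion from smoothed signal was tested on 40000 simulated tags and recovered 99.9% of them.

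The regions named in the text follow a rule set before the data were examined: the 20 X peaks with the highest mean RNase log2 fold, the 10 highest peaks off X, the 5 X peaks with the largest and the 5 with the smallest RNase minus biotin difference among those with at least 20 tags in each roX2 library, and the 5 highest bins of the sense control. A single X peak outside the rule, X 9814674 to 9814873, was named after its values were seen because it was the peak lower in both RNase libraries than with biotin elution. Fixed lists of genes, a GA-rich motif and the place of peaks in genes needed a dm3 genome or annotation and were not analysed here. The gene table at hand belongs to another assembly, and none of its coordinates was used. No test compared groups: only RNase elution had more than 1 library, which leaves a single residual degree of freedom. The alternatives were: each RNase library alone, the sense control as denominator, scaling to autosomal tags, 1-kb windows at peaks, 5 tags added, a fold of 8, 500-bp bins, 20 input tags, a distance of 20 kb, the peaks at or above the median fold and the X share of bins as expectation. Thinning to equal depth and leaving out peaks with a higher neighbour were added after the data were seen. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.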

Results

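Chromatin bound by the non-coding RNA roX2 was mapped in Drosophila S2 cells, a male embryonic line that carried a tagged copy of the dosage compensation protein MSL3. roX2 belongs to the RNA and protein complex that acts on the single X of male flies. In CHART-seq, biotinylated oligonucleotides complementary to an RNA capture that RNA from a chromatin extract, and the DNA recovered with it is sequenced. The series held 5 libraries in 4 groups. The roX2 capture was eluted with biotin in 1 library and with RNase H in 2 replicate libraries. A capture with sense oligonucleotides and an input library, 1 of each, served as controls. The elution used for the sense control was not stated in the labels. Nothing in the labels said whether the 2 RNase replicates came from separate cultures, so their spread may be technical. All coordinates are of the dm3 build.

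The deposited tag densities gave an estimated 4867180 tags on X, 2L, 2R, 3L, 3R and 4 for RNase replicate 1 and 2585925 for RNase replicate 2. The biotin-eluted library held 11715533 tags, the sense control 11620725 and the input 23561373. The median 1-kb bin held 28.0 and 15.8 tags in the RNase libraries, 73.4 in the biotin-eluted library, 64.2 in the sense control and 190.0 in input. With 1 library per group apart from the RNase elution, no test between groups was run, and differences from the other groups had no replicate check. Exact tests on peaks or bins describe lists from these libraries, and all intervals cover counting error only.

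The first comparison asked how strongly each capture recovered the X relative to the autosomes. RNase-eluted roX2 chromatin held 3.38 ± 0.51 (SD, n = 2) times the X to autosome ratio of input, with 3.74 in replicate 1 and 3.02 in replicate 2. Biotin-eluted roX2 chromatin held 1.99 times the input ratio, which lay below both RNase libraries by more than their spread. The sense control was at 1.04. X tags made up 33.2% of replicate 1 (95% exact binomial interval 33.1 to 33.2) and 28.6% of replicate 2 (28.5 to 28.7). Their share was 20.9% with biotin elution (20.9 to 20.9), 12.2% in the sense control (12.2 to 12.2) and 11.7% in input (11.7 to 11.7). Chromosome 4, the small autosome, stood below the large autosomal arms in every capture, at 0.85 and 0.87 times input with RNase elution, 0.65 with biotin elution and 0.78 in the sense control.

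**Figure D1:**
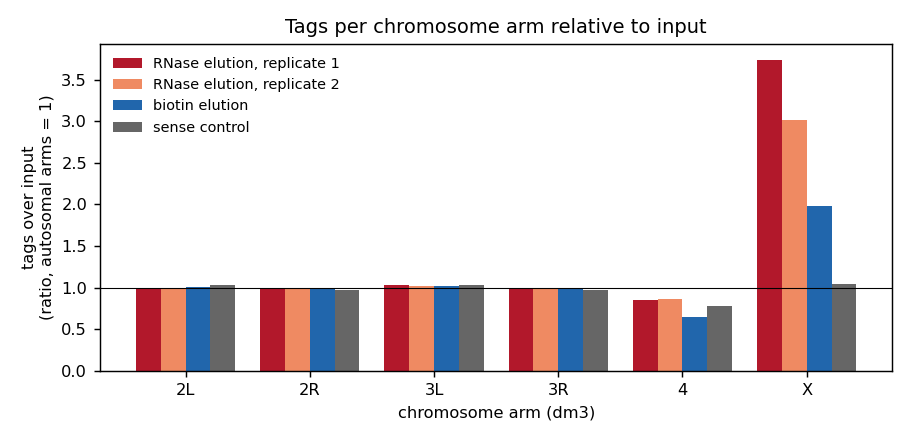
Tags per chromosome arm over input, as a ratio in which the 4 large autosomal arms together equal 1, for 4 libraries (1 bar per library, no error bars). X stood at 3.74 and 3.02 with RNase elution, 1.99 with biotin elution and 1.04 in the sense control, while 2L, 2R, 3L and 3R stayed near 1.

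The deposited peak list, made by the authors on both RNase libraries combined, placed nearly all sites on X. Of 711 peaks, 636 lay on X, 13 on 2L, 17 on 2R, 14 on 3L and 17 on 3R. A further 4 lay on XHet, 4 on 2RHet, 1 on 3LHet and 5 on 3RHet, the sequences of each arm assigned to heterochromatin. On the 6 main arms X held 636 of 697 peaks, or 91.2% (95% exact interval 88.9 to 93.2), where the X share of input tags was 11.7%. This was a 7.80-fold excess, with a one-sided exact binomial log10 p of -507. With the X share of bins, 18.4%, as the expectation, the excess was 4.96-fold. Neighbouring X peaks lay a median of 9030 bp apart, and the widest gap ran from 20393063 to 20901169. Full 1-Mb windows of X held 16 to 51 peaks with a median of 26.5, the highest number in the window from 11 to 12 Mb.

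Peaks that followed a higher one were common in the list. Of 88 pairs of neighbouring X peaks 3 to 3.5 kb apart, the one on the left (lower coordinate) had the higher RNase fold in 81, with an exact two-sided binomial p of 4.48e-17. In all, 170 of the 636 X peaks had a higher listed peak within 5 kb. Whether these are sites of their own was not settled. This grouping was chosen after the data were seen.

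At the X peaks, roX2 capture recovered chromatin far above input with both elutions, and the sense capture did not. The median log2 fold over input was 3.52 and 3.30 in the RNase libraries, a mean of 3.41 ± 0.15 (SD, n = 2) or 10.6-fold. It was 2.13 with biotin elution, or 4.36-fold, and -0.39 in the sense control, or 0.76-fold. A fold of 4 or more was reached at 602 and 556 of the 636 peaks in the RNase libraries, at 335 with biotin elution and at 25 in the sense control. The peaks were chosen on the RNase libraries, so the biotin-eluted and sense libraries are the ones that did not choose them. None of 10000 random sets of X windows outside peaks, matched on input tags, had a median as high as the peaks in any roX2 library. The medians of the random sets were centred on 0.18 and 0.39 with RNase elution and -0.05 with biotin elution. In the sense control 1117 of the 10000 sets were as high as the peaks. Peaks that had a higher peak within 5 kb were then left out. The medians without them were 4.09 with RNase elution, 2.64 with biotin elution and -0.35 in the sense control. This filter removes peaks for a lower RNase fold than a neighbour, so the rise with RNase elution was built into it. Biotin folds followed RNase folds across X peaks, so their rise is not separate evidence. Scaling to autosomal tags instead of all main arms shifted every fold by 0.40 and 0.30 on the log2 scale in the RNase libraries, 0.15 with biotin elution and 0.005 in the sense control, since X tags themselves filled part of the total.

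The 20 X peaks highest with RNase elution had mean folds from 119 to 221 over input. The same 20 stood 39.8- to 132-fold over input with biotin elution. Their sense control folds ran from 0.16 to 9.59, with 4 of the 20 at 4-fold or more and 8 below input. Input held 9.68 to 46.3 tags in these 200-bp windows. The highest, X 5682644 to 5682843, stood 244-fold (95% counting interval 179 to 357) and 199.97-fold (146 to 294) over input in RNase replicates 1 and 2. It was 91.0-fold with biotin elution and 0.64-fold in the sense control. The second, X 11473919 to 11474118, stood at 214- and 186-fold with RNase elution. It had the highest biotin fold of all X peaks, 132 (96.4 to 200.2), and its sense control fold of 9.59 (6.72 to 14.9) ranked 2 of 636. The third, X 18782059 to 18782258, reached 206- and 159.8-fold with RNase elution and 57.8-fold with biotin elution, over 10.1 input tags. Next came X 11291639 to 11291838 at 177- and 154-fold, and X 16502019 to 16502218 at 153- and 137-fold. Gene annotation of the dm3 build was not used here, so the peaks are named by position.

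**Figure D2:**
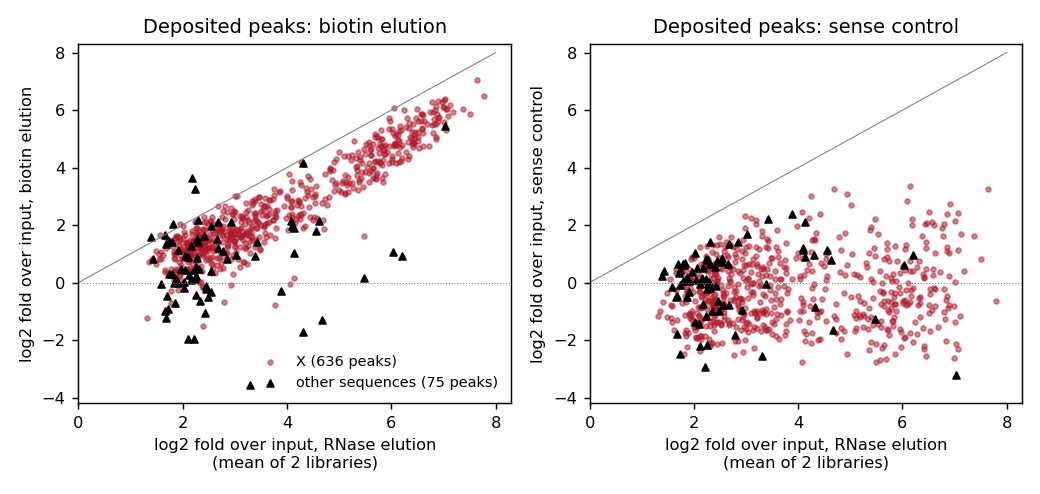
Log2 fold over input at each of the 711 deposited peaks with biotin elution (left) and in the sense control (right), against the mean log2 fold of the 2 RNase libraries; red points are the 636 X peaks, black triangles the 75 others, and the solid line marks equal folds. With biotin elution X peaks rise along the line but below it, by a median of 1.25. The sense control folds at X peaks correlate only weakly with the RNase folds, at 0.12 (Pearson) for each RNase library. They spread from -2.78 to 3.34, with a median of -0.39.

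The 61 peaks on 2L, 2R, 3L and 3R had median log2 folds of 2.22 and 2.31 with RNase elution, 0.93 with biotin elution and 0.23 in the sense control. A fold of 4 or more was reached at 40 of the 61 in both RNase libraries, at 9 with biotin elution and at 3 in the sense control. The 10 peaks on 2RHet, 3LHet and 3RHet had medians of 2.23 and 3.03 with RNase elution but -0.61 with biotin elution and -1.03 in the sense control. Relative to autosomes and input, these whole sequences stood at 0.48, 0.49 and 0.43 with biotin elution and 0.53, 0.55 and 0.48 in the sense control. With RNase elution they stood at 0.89 to 0.98. The low biotin and sense medians therefore do not show depletion particular to these peaks.

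Among the 10 highest peaks off X, XHet 79117 to 79316 was the highest. It stood 137- and 125-fold over input with RNase elution, 43.7-fold with biotin elution and 0.11-fold in the sense control. Of the others, 2L 10410035 to 10410234 stood 20.4- and 19.3-fold with RNase elution and nearly as high, 17.7-fold, with biotin elution. The peaks 3L 3903517 to 3903716 and 2R 19758136 to 19758335 reached 26.1- and 24.6-fold in RNase replicate 1 and 4.41- and 3.44-fold with biotin elution. By contrast, 3RHet 2308407 to 2308606 stood 39.1- and 50.9-fold with RNase elution and 1.11-fold with biotin elution (0.49 to 2.31). With biotin elution 3RHet as a whole stood at 0.43 times the input ratio to autosomes. Both 3R 8293144 to 8293343 and 3RHet 1953822 to 1954021 lay at least 19.2-fold above input in each RNase library and at 0.30-fold (0.0046 to 1.41) and 0.40-fold (0.036 to 1.51) with biotin elution. The remaining peak on 3L, 16397432 to 16397631, stood at 16.6- and 18.7-fold with RNase elution and 2.06-fold with biotin elution. For 2 further peaks the input held 0.78 and 1.91 tags, so their folds are poorly bounded. At 2L 10156600 to 10156799 the fold in replicate 1 was 62.8 (17.2 to 4395), and at 3RHet 1171852 to 1172051 it was 52.6 (19.1 to 647).

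The next comparison set the elution strategies side by side at the X peaks. The peaks were called on the RNase libraries, and that choice favours a higher fold in them than in the biotin-eluted library. RNase elution gave a higher fold than biotin elution by a median of 1.25 ± 0.16 on the log2 scale, or 2.37-fold. The SD is over the 2 RNase libraries, each set against the same biotin-eluted library, so it holds no spread of biotin elution. The median of RNase replicate 2 minus replicate 1 was -0.25. Both RNase libraries were above the biotin-eluted library at 611 of 636 peaks. Both were below it at 1, X 9814674 to 9814873, where the folds were 3.73, 3.96 and 4.10. Across peaks, which are not independent replicates, the log2 folds of RNase replicate 1 and the biotin-eluted library had a Pearson correlation of 0.93. The simulated value for unchanged libraries set against the same input was 0.26, and the covariance was 2.58 against 0.10 simulated. With a separate random part of the input for each library the correlation was 0.87. The biotin-eluted library and the sense control correlated at 0.06, against 0.40 simulated, with a covariance of 0.11 both observed and simulated. Each RNase library correlated with the sense control at 0.12, against 0.31 and 0.27 simulated for replicates 1 and 2. Their covariance with the sense control was 0.22 in each, above the 0.11 simulated. Elution, oligonucleotides and hybridization conditions differed together between the strategies, so the difference belongs to the whole procedure.

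The gap between elutions was uneven over single X peaks. Among the 364 X peaks with at least 20 tags in each roX2 library, X 20067434 to 20067633 had the largest difference, 3.97 on the log2 scale. It stood 16.0- and 19.1-fold over input with RNase elution and 1.11-fold with biotin elution. X 13224269 to 13224468 followed with a difference of 3.86, X 3686104 to 3686303 with 2.87, X 3596679 to 3596878 with 2.52 and X 10675149 to 10675348 with 2.49. In the sense control, X 3596679 was also 9.47-fold and X 13224269 4.60-fold (2.40 to 9.40) over input. At the other end, X 12974299 to 12974498 had a difference of -0.006, with 74.9- and 59.1-fold by RNase and 66.8-fold by biotin elution. The others of the 5 lowest were X 1289969 to 1290168 (0.01), X 19472924 to 19473123 (0.07), X 9580699 to 9580898 (0.18) and X 6186679 to 6186878 (0.23). The SD over peaks was 0.61 for the RNase minus biotin difference and 0.42 for the difference between the RNase libraries. With 1 biotin-eluted library, an effect of elution on this spread cannot be told apart from variation between preparations.

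A single rule applied to every library, a fold over input of 4 or more in 1-kb bins with at least 10 input tags, called bins on X in the roX2 libraries and mostly elsewhere in the sense control. Of 115055 bins, 21158 or 18.4% lay on X. Both RNase libraries called 2047 bins on X and 51 off X, so 97.6% of their shared bins were on X. Alone, replicate 1 called 2518 on X and 71 off X, and replicate 2 called 2245 and 115. Unchanged libraries simulated against the same input at these depths called 1 bin off X for replicate 1 and 15 for replicate 2. The biotin-eluted library called 1556 on X and 798 off X, 66.1% on X. The sense control called 522 on X and 1922 off X, 21.4% on X, for which an exact two-sided binomial test against the X share of bins gave p = 0.000207 over bins that are not independent. With the sense control as the denominator, the counts off X rose to 724 with RNase elution and 2184 with biotin elution, and scaling to autosomal tags gave 115 with RNase elution. With a fold of 8 the counts on X fell to 1074, 596 and 49 for RNase elution, biotin elution and the sense control, and in 500-bp bins they were 3987, 3186 and 1334.

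The X bins of both roX2 elutions overlapped. Of the 2047 RNase-enriched X bins, 1257 or 61.4% were also enriched with biotin elution, where independent lists would share 151. The odds ratio was 100.1 by Fisher's exact test and 89.7 with a separate random part of the input for each list. The sense control shared 63 of the 2047, or 3.08%, where independent lists would share 50.5, with a two-sided Fisher exact p of 0.0714. With separate parts of the input it shared 65 of 2043, where independent lists would share 51.3, with a Fisher exact p of 0.0444. Off X, the biotin-eluted library and the sense control shared 274 of their 798 and 1922 bins, where independent lists would share 16.3, with an odds ratio of 29.0. The RNase-enriched bins off X shared 7 of 51 with the biotin-eluted library, where independent lists would share 0.43, and 11 of 51 with the sense control, where they would share 1.04. The odds ratios were 18.7 (two-sided Fisher exact p = 2.61e-07) and 13.2 (p = 5.77e-09), and 20.5 and 11.1 with a separate random part of the input for each list. Libraries simulated with no change shared 0 and 1 bins. Of the 51 RNase-enriched bins off X, 30 lay within 2 kb of a deposited peak, and these peaks were called on the same RNase libraries. Of the biotin-enriched and sense-enriched bins off X, 9 of 798 and 6 of 1922 did. At the 1922 bins off X that the sense control called, the median fold over input was 4.94 in the sense control itself, 1.66 with biotin elution, and 1.24 and 1.26 with RNase elution. On the log2 scale the RNase medians there were 0.31 and 0.33, above those of all autosomal bins, -0.51 and -0.39; biotin elution was at 0.73 against -0.40. Over all bins off X, RNase replicate 1 and the sense control had a covariance of 0.35 against 0.012 simulated.

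None of the 5 highest bins of the sense control reached 4-fold in either RNase library. X 3347001 to 3348000 stood 26.0-fold over input in the sense control, 2.97-fold with biotin elution, and 1.63- and 0.84-fold with RNase elution. X 14915001 to 14916000 stood at 21.6-fold in the sense control, 7.61-fold with biotin elution, and 1.75- and 1.53-fold with RNase elution. 3R 16900001 to 16901000 was as high with biotin elution, 22.5-fold, as in the sense control, 20.5-fold, and reached 1.64- and 1.01-fold with RNase elution. The remaining pair, 2R 4998001 to 4999000 and 2L 8741001 to 8742000, stood at 19.7- and 19.1-fold in the sense control and 3.68- and 2.50-fold with biotin elution. With RNase elution 2R 4998001 stood at 0.96- and 0.92-fold. In RNase replicates 1 and 2, 2L 8741001 stood at 1.53- and 3.58-fold, and the counting interval in replicate 2, 1.93 to 5.98, includes 4.

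**Figure D3:**
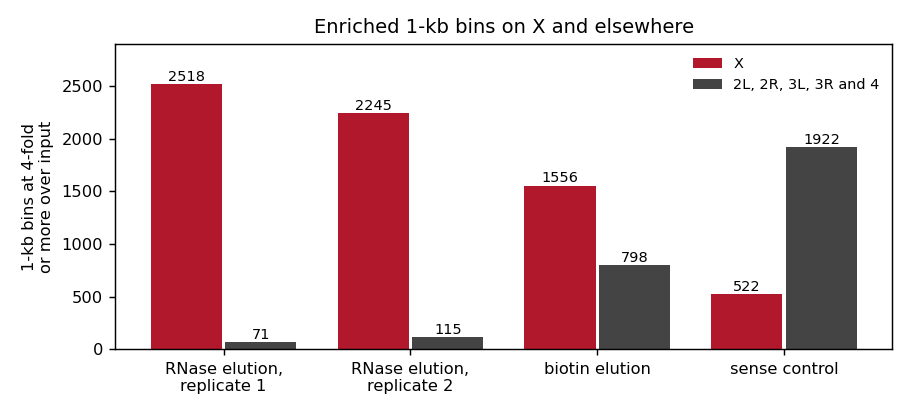
Number of 1-kb bins at 4-fold or more over input on X (red) and on 2L, 2R, 3L, 3R and 4 (grey) in each capture library. RNase elution called 71 and 115 bins off X, biotin elution 798 and the sense control 1922.

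The last comparison asked how far from the peaks the X stood above the autosomes. Relative to the median autosomal bin, X bins within 1 kb of a peak centre had a median log2 fold of 3.49 ± 0.30 (SD, n = 2) with RNase elution, 2.34 with biotin elution and -0.09 in the sense control. At 2 to 5 kb the values were 1.61 ± 0.21, 1.06 and -0.26, and at 5 to 10 kb they were 0.71 ± 0.08, 0.44 and -0.01. Over all 16473 X bins more than 5 kb from any peak the median was 0.34 ± 0.03 with RNase elution, 0.22 with biotin elution and 0.12 in the sense control. Beyond 20 kb it was 0.26 ± 0.02, 0.18 and 0.16. The 4 large autosomal arms differed from their joint median by -0.04 to 0.05 in RNase replicate 1 and by -0.10 to 0.07 in the sense control, and chromosome 4 by -0.26 and -0.48. With the sense control as the denominator, the value beyond 5 kb fell to 0.13 with RNase elution and 0.022 with biotin elution.

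The mean profile at X peaks was sharp in the roX2 libraries. At the peak centres RNase replicates 1 and 2 held 178 and 150.0 tags per kb for each 1e+06 tags of the library, the biotin-eluted library 72.2, the sense control 6.06 and input 5.63. The width midway between the centre and the flanks was 1000, 800 and 1000 bp in the 3 roX2 libraries, with a smoothing bandwidth of 200 bp. Widths were read in steps of 100 bp on each side, so the lower value of replicate 2 may come from this grid. The profile over all peaks held 634 X peaks. Over all peaks the profile had a second rise 3.2 kb to the left, 75.2 tags per kb in replicate 1 against 24.1 at the same distance on the right. Around the 121 X peaks with no other peak within 10 kb, a choice that by itself removes listed neighbours, replicate 1 showed no such rise. It fell on the left from 24.0 tags per kb at 2.5 kb to 18.4 at 3.2 kb. On the right it fell from 15.5 to 11.6 over the same distances. The centre stood 17.4-fold above the density at 5 kb in replicate 1, against 5.03-fold over all peaks.

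**Figure D4:**
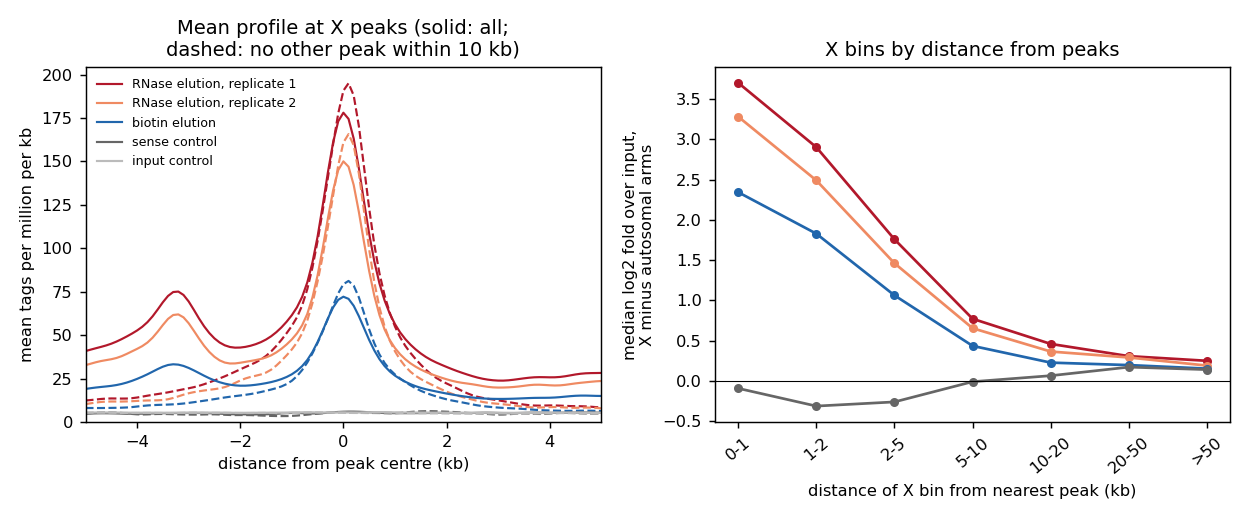
Left, mean tags per kb for each 1e+06 tags of the library around X peak centres for all peaks (solid) and for the 121 with no other peak within 10 kb (dashed), by distance in kb; right, median log2 fold over input of X bins minus that of autosomal bins, by distance from the nearest peak in kb, 1 line per library. The roX2 libraries fall from 3.70, 3.28 and 2.34 within 1 kb to 0.25, 0.19 and 0.15 beyond 50 kb, where the sense control is at 0.14.

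**Figure D5:**
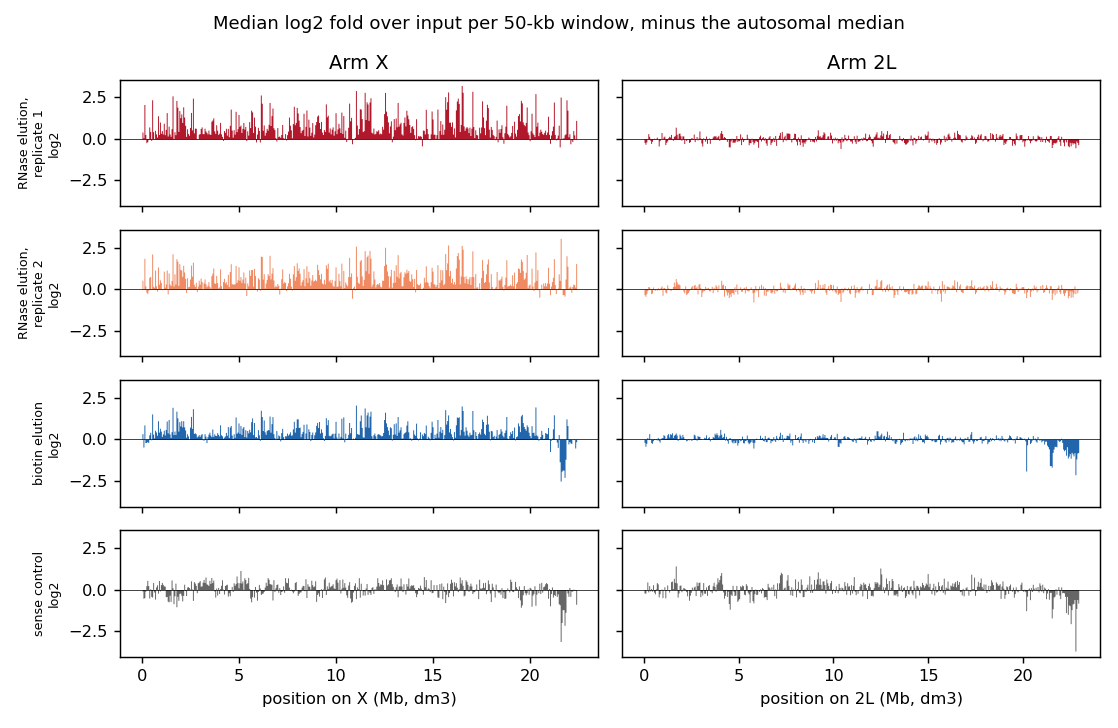
Median log2 fold over input per window of 50 kb along X (left) and 2L (right), minus the autosomal median, for the 4 capture libraries (rows). The roX2 libraries stand above 0 over most of X and near 0 on 2L, and the biotin-eluted library and sense control dip at the end of both arms near the centromere. In X bins more than 20 kb from any peak the sense control too stood above autosomes, by 0.16. The value there was 0.18 with biotin and 0.26 with RNase elution.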

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

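At 2 of the 10 highest peaks off X, the biotin-eluted library went the opposite way from both RNase libraries relative to input. At 3RHet 1953822 to 1954021 its log2 fold was -1.30, against 4.48 and 4.85 with RNase elution, and 3RHet as a whole stood at 0.43 times the input ratio to autosomes with biotin elution, 0.48 in the sense control and 0.89 and 0.90 with RNase elution. At 3R 8293144 to 8293343 it was -1.73, against 4.36 and 4.26. The difference was not tested, since the biotin elution has 1 library. Both peaks held few tags with biotin elution, 1.54 and 0.69, and the counting intervals of the biotin folds, 0.036 to 1.51 and 0.0046 to 1.41, include 1 but lie below those of both RNase libraries. The sense control was also below input at both, at 0.32- and 0.56-fold.

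Signal also appeared on sequences outside the comparisons. XHet stood at 4.39 and 3.63 times the input ratio to autosomes in the RNase libraries and at 1.70 with biotin elution, above the sense control at 0.65. Within 5 kb of the peak at XHet 79117 lay 62.6% and 56.5% of the XHet tags of the RNase libraries and 55.3% with biotin elution, against 9.16% in input. Without that stretch the ratios were 1.81, 1.74 and 0.84, and 0.62 in the sense control. YHet ratios were 10.6 and 2.66 with RNase elution and 4.41 with biotin elution, against 2.07 in the sense control, from 96, 14, 114 and 59 tags over 58 in input.

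Unplaced sequences and the mitochondrial genome have values for the RNase libraries alone, so no control level stands beside them. U held 47418 and 27747 tags in replicates 1 and 2, Uextra 92983 and 56802, and the mitochondrial genome 1188 and 699.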

How the results depend on the processing

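Of 91 values under alternatives, 53 stayed within the spread or count limit of the reported value, 38 moved and none reversed; thinning to equal depth and leaving out peaks with a higher neighbour were chosen after seeing the data. The excess of deposited peaks on X stayed past its test, between 4.96- and 8.26-fold. Thinning the capture libraries to 2585925 tags left all counts within 1.5 times. The cause was not tested for any value below, except where fewer or smaller bins or peaks change a count by construction. Using 1 RNase library at a time, the overlap of RNase-enriched X bins with biotin elution was 51.1% to 56.4% and the RNase bins off X were 71 to 115, both from calling on 1 library. With the sense control as denominator, the overlap was 72.1%, the X to autosome ratio with biotin elution 1.90, the bins off X 2184 with biotin and 724 with RNase elution, the median log2 fold at X peaks 2.68 and 3.90, and the X excess beyond 5 kb 0.022 and 0.13. With autosomal scaling, the RNase minus biotin difference was 1.45, the overlap 56.9%, the RNase bins off X 115, and the medians at X peaks 2.28 with biotin and 3.76 with RNase elution. In 1-kb windows the biotin median was 2.06. With 5 tags added it was 2.00 and the sense median -0.072. At a fold of 8 the overlap was 53.0%, with 1074, 596 and 49 bins on X and 11, 62 and 162 off X for RNase elution, biotin elution and sense control. In 500-bp bins the counts were 3987, 3186 and 1334 on X and 130, 2158 and 4907 off X. Beyond 20 kb the X excess was 0.26, 0.18 and 0.16. Without peaks that had a higher neighbour within 5 kb the medians at X peaks were 4.09, 2.64 and -0.35. That filter uses the RNase folds themselves, so it raises the RNase median by construction.

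Keeping 1 read per start position and strand was not run, since smoothed densities hold no reads. The motif alternatives (no mismatch, 1-kb window) and the alternative for peaks in exactly 1 gene were not run, for want of a dm3 genome and annotation here. No paired analysis was possible because only the RNase elution has numbered replicates. Depth limits single bins most in RNase replicate 2, with a median of 15.8 tags per bin.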

Other observations

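The tests of the X shift in the sense control, of unlisted peaks at 5 to 20 kb and of the sense rank of 1 X peak, and the grouping of neighbouring peaks, were chosen after the results were seen. The test at mirrored positions was set before its result.

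Recovery of heterochromatin differed between libraries. Relative to autosomes and input, 2LHet, 2RHet, 3LHet and 3RHet stood at 0.90, 0.96, 0.90 and 0.89 in RNase replicate 1 and at 0.91, 0.98, 0.90 and 0.90 in replicate 2. With biotin elution they stood at 0.40, 0.48, 0.49 and 0.43, and in the sense control at 0.41, 0.53, 0.55 and 0.48. The biotin-eluted library and the sense control thus lay together, below input and below both RNase libraries, on these 4 sequences. Chromosome 4 showed the same order for biotin elution, with a median bin at -0.72 on the log2 scale against autosomes, -0.48 in the sense control, and -0.26 and -0.23 with RNase elution. The elution of the sense control is not stated, and the RNase densities cover 15 sequences against 12 in the others, so elution and processing were not separated here.

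Many X peaks were listed just to the right of a higher one: the left peak was higher in 81 of 88 pairs 3 to 3.5 kb apart, in 41 of 54 pairs 4 to 5 kb apart, in 38 of 84 pairs 5 to 7 kb apart (exact binomial p = 0.445) and in only 30 of 80 pairs 7 to 10 kb apart (exact binomial p = 0.0330, the opposite direction), and no pair was closer than 3045 bp. A candidate explanation is a rule of the list that takes a shoulder of a higher peak once a minimum distance is passed. For the 81 lower peaks, the median RNase log2 fold minus that at the mirrored position, on the other side of the higher peak, was 0.40, with quartiles of -0.76 and 1.503. The bounds set in advance, under 0.3 for a shoulder and above 1 for a site of its own, left this test undecided, and no biological explanation was tested. Of the 81, 16 were local maxima against 500 bp on either side in both RNase libraries, as were 18 of the mirrored positions and 288 of the 466 X peaks without a higher neighbour within 5 kb. The 81 were thus local maxima no more often than the mirrored positions. No bound had been set in advance for this count. A weak site on the slope of a higher peak can fail to be a local maximum, so the count does not decide whether they are sites of their own.

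X bins 5 to 20 kb from a peak stood above the autosomes by 0.52 ± 0.07 (SD, n = 2) with RNase elution. The shift was 0.31 with biotin elution and 0.037 in the sense control. This comparison was chosen after its values were known and rests on 1 sense library of unstated elution. The sense shift also changed with distance from peaks, from -0.26 at 2 to 5 kb to 0.17 at 20 to 50 kb. It therefore cannot settle whether any CHART recovers X chromatin better. The lower quartile of these bins was shifted by 0.43 more with RNase elution than in the sense control, so the shift was not limited to the highest bins. That test too was chosen after the results were seen, and it does not decide the cause. A lower level of roX2 along X around its peaks is a hypothesis. Neither it nor chromatin drawn in with the peaks over such distances was tested. Beyond 20 kb the sense control shifted by 0.16, against 0.26 ± 0.02 with RNase elution and 0.18 with biotin elution, so a recovery of X common to any CHART cannot be told apart from roX2 there. The test set in advance for tags that leak from peaks, a lower quartile above autosomes, gave 0.18 ± 0.05, but its bound was wrong because the sense control reached 0.15, and leakage cannot be told apart either.

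Off X, the biotin-eluted library and the sense control shared 274 enriched bins, where RNase elution had median log2 folds of 0.58 and 0.62, against -0.51 and -0.39 in all autosomal bins, so it too was raised there. Noise of the shared input does not account for it: with a separate random part of the input for each library the odds ratio was 29.8, where 10 had been set in advance as the bound. Thin input does not account for it either, since the shared bins held 0.995 times the median input tags of all bins. Chromatin held by the beads or the oligonucleotides without roX2 may account for these bins, as may a difference between preparations. Neither was tested, since the labels do not state the elution of the sense control and no sense capture known to be eluted with RNase H was analysed here.

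The X peak with the highest biotin fold, X 11473919 to 11474118, may hold DNA of the captured RNA's own gene, which both sense and roX2 oligonucleotides could bind. The test was the rank of its sense control fold among the X peaks. Its sense control fold of 9.59 ranked 2 of 636 X peaks, where the highest 5% began at 3.53. This fold was known when the rank was chosen as the test. The outcome was therefore fixed, and the rank neither supports nor excludes the hypothesis. Another X peak had a higher sense control fold, and the place of the gene in dm3 was not looked up here.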
